A study of Homo sapiens with 15 samples.

How the data were processed

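Poly(A) RNA from i3Neurons was extracted with TRIzol and made into directional libraries, per the labels' protocols. The 15 libraries fall into 5 groups of 3. shScramble, shSON and shSRRM2 are day 14 neurons, and GGGGCC2 and GGGGCC186 are day 10 neurons. Trim Galore 0.6.7, HISAT2 2.2.1 and Subread 2.0.1 and the build hg38/GRCh38 are named per the submitters' processing notes. The labels do not name the caller of the splicing events or its version. The deposited tables carry MATS in their names and have the layout of rMATS output from reads that span junctions.

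The authors deposited 15 tables, for 5 event types in each of 3 comparisons: cassette exons, retained introns, alternative 3′ and 5′ splice sites, and mutually exclusive exons. For each event, the deposited values are raw junction read counts of the inclusion and skipping forms for every library, the lengths of both forms, the inclusion level, the inclusion difference between groups, and the p-value and false discovery rate of the authors' test. The inclusion level (percent spliced in, PSI) is the length-scaled inclusion reads over the length-scaled reads of both forms. It was recomputed from the deposited reads, and all values used here come from those reads except where the authors' deposited table is named. For retained introns a higher PSI means more retention.

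Groups were matched to the value columns from the names of the compared groups in their order. In the knockdown tables this order was checked: the first group's reads were identical between the shSON and shSRRM2 tables for 84233 of 84233 shared cassette exons, 12650 of 12650 introns and 34398 of 34403 alternative 3′ splice sites, as a shared control requires. For GGGGCC186 the same order was assumed, and no targeted gene checks it. Values within a cell carry no replicate number, so replicate numbers name only a position. No pair of libraries in a group agreed within sampling noise (chi-square per degree of freedom 3.11 to 5), so all counted as separate. Events on the Y chromosome and XIST were left out.

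An event was tested if it had a mean of at least 10 reads per library over 6 libraries and at least 10 reads of each form in all. PSI was moved to a log2 odds scale after adding 0.5 reads to each form and tested with limma 3.58.1 in R 4.3.3, with the prior variance trended on the expected sampling variance, two-sided. P-values were adjusted by Benjamini-Hochberg within each event type. An event was called at an adjusted p under 0.05 with a difference in mean PSI of at least 0.1. Each comparison was fitted to its 6 libraries alone. The knockdowns were compared directly on the 6 knockdown libraries, and differences of effects were fitted over 12 libraries with the experiment as a term. Tables were read with data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and figures drawn with matplotlib 3.10.9.

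Gene abundance was approximated by the length-scaled junction reads of each gene's most-read event, as reads-per-million (RPM), on the log2(value + 1) scale, in genes with a mean of at least 10 reads, with limma and a variance trend, two-sided, adjusted over genes. This fold change understates the change of low genes. Gene lists were compared with 10000 random sets matched on quintiles of tested events and reads, one-sided, adjusted over 16 lists. Exon and intron lengths were compared between called and uncalled events matched on quintiles of reads by permutation with 100000 resamples, two-sided, adjusted over 24 tests. Exons and introns were annotated with GENCODE 29. GC content was not analysed here, because no genome sequence was used.

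The main tests of each comparison, their thresholds, the gene lists and the rule for named genes were set before the data were examined. The closing section names the further tests chosen after a result was seen. The rule takes SON and SRRM2. Per comparison and direction it takes the 4 cassette exons, 4 introns and 1 event of each other type with the largest difference among called events with at least 20 reads per library, groups that do not overlap and an authors' false discovery rate under 0.05, 1 event per gene. It adds up to 4 genes per list and the 6 largest events called in both knockdowns. For marker and response lists the rule takes 2 genes, and those named beyond that were chosen after their values were seen. The splicing lists are those counted in the report. The marker lists cover neurons, glutamatergic and GABAergic neurons, pluripotent cells, neural progenitors, proliferating cells, astrocytes, oligodendrocyte lineage, microglia and fibroblasts. The response lists cover p53, integrated stress, heat shock and interferon.

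The models were tested on simulated data with known changes. The spread between simulated libraries was set (overdispersion 0.01 for events and for genes) and not estimated from these libraries. The shares called and the false calls hold for that spread only. In the real GGGGCC186 comparison, splits that mixed the groups called up to 18 events with limma. With 200 changed cassette exons among 39378, limma called 8% of changes of 0.3 in PSI in shSON (23.5% above 100 reads) with 0 false calls, and with 3938 changed it called 55.1% (91.4%) with 2 false calls. In GGGGCC186 the shares were 4% (12.5%) with 200 changed among 39770 and 50.6% (88.7%) with 3976 changed. In shSRRM2 they were 10% (30%) with 200 changed among 35874. For abundance, 2-fold falls were called in 89% of simulated genes in shSON, 94% in shSRRM2 and 90% in GGGGCC186. Alternatives covered the authors' false discovery rate, a quasi-binomial model, no variance trend, 1 read added, a mean of 20 reads, no read filter, PSI differences of 0.05 and 0.2, 1 event per gene and type, all 9 knockdown libraries in 1 fit, other abundance scalings and leaving out each library. Binomial intervals were taken over events or genes, which they treat as independent, and they leave out the spread between libraries. Results for some genes that the rule takes are not reported here.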

Results

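Poly(A) RNA was sequenced from i3Neurons, human neurons made from induced pluripotent stem cells by an inducible transcription factor. The 15 libraries form 5 groups of 3. At day 14, neurons carried a scrambled short hairpin RNA (shScramble) or hairpins against SON (shSON) or SRRM2 (shSRRM2), large proteins that build the core of nuclear speckles, the nuclear bodies rich in splicing factors. At day 10, neurons expressed either 2 GGGGCC repeats (GGGGCC2) or 186 of them (GGGGCC186). A long GGGGCC repeat in C9ORF72 is a known cause of amyotrophic lateral sclerosis and frontotemporal dementia. Junction reads (in M, megareads) summed over the listed splicing events ranged from 48.8 M to 80.8 M per library, and a read can count in several events. The median cassette exon had 56 to 96 reads per library. The labels do not say that the 3 libraries of a group came from separate cultures, so all p-values measure only the spread between these libraries, which may be technical.

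SON, on chromosome 21 at 33542618 to 33577481 on the plus strand of GRCh38, fell in the shSON neurons to 31.4 ± 6.82 junction reads-per-million (RPM) from 98.7 ± 7.81 in shScramble (SD, n = 3), or 31.8% of control. The change was -1.64 on the log2 scale (SE 0.147, limma adjusted p = 2.85e-08). SRRM2, on chromosome 16 at 2752329 to 2772538 on the plus strand, fell in the shSRRM2 neurons to 38.8 ± 5.77 from 87.0 ± 17.6, or 44.6% of control (log2 change -1.13, SE 0.146, limma adjusted p = 1.18e-05). Neither hairpin lowered the other gene: SRRM2 rose in shSON from 112 ± 2.90 to 143 ± 17.4 (log2 change 0.34, adjusted p = 0.0195), and SON in shSRRM2 was 97.9 ± 5.88 against 90.1 ± 6.59 (log2 change 0.12, adjusted p = 0.408, 95% interval -0.09 to 0.328). In GGGGCC186, SON (log2 change 0.07, adjusted p = 0.979) and SRRM2 (log2 change -0.10, adjusted p = 0.977) did not pass the test. Exact two-sided permutation tests of 3 libraries against 3 cannot go below p = 0.1, which SON reached in shSON and SRRM2 in shSRRM2. These abundances come from the single most-read splicing event of each gene, so the shScramble level differs between comparisons with different event lists.

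**Figure D1:**
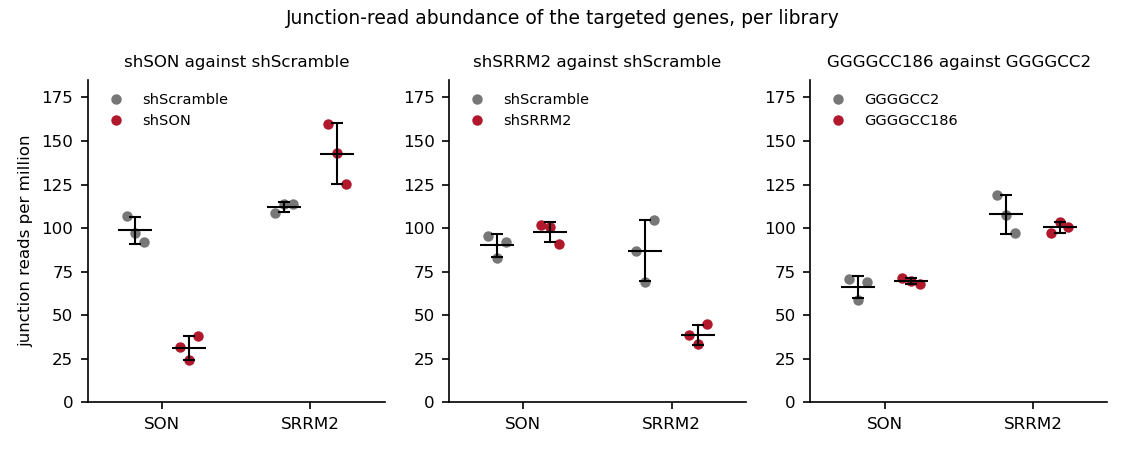
Junction-read RPM of SON and SRRM2 (vertical axis) in each library (points), with the mean and SD of 3 libraries (black). SON averaged 31.4 in shSON against 98.7 in shScramble, SRRM2 averaged 38.8 in shSRRM2 against 87.0, and neither gene passed the test in GGGGCC186.

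The first comparison asked how splicing changed when SON was depleted. Called events of any type and direction lay in 2318 of the 9745 genes tested (23.8%), with cassette exons called in 1888 of 8253 genes and introns in 1026 of 3239. Of 5875 called cassette exons, 5551 had lower inclusion and 324 higher. Of 1978 called introns, 1902 were retained more and 76 less. The largest rises in retention included an intron of PRPF40B, a splicing factor associated with the U1 particle, from 0.0% ± 0.0 to 100% ± 0.0 of its junction reads (SD, n = 3). Exons of RNH1, the cytosolic ribonuclease inhibitor, went the other way, from 97.0% ± 5.1 inclusion to 0.4% ± 0.7. Alternative 3′ splice sites (241 higher and 405 lower), alternative 5′ splice sites (108 and 423) and mutually exclusive exons (534 and 389) brought the total to 9953 of 81121 events tested with limma at an adjusted p under 0.05 and a PSI difference of at least 0.1. Higher inclusion made up 5.5% of called exons (exact 95% binomial interval 4.9 to 6.1), against 39.8% of all tested exons. It made up 96.2% of called introns (95.2 to 97), against 77.4% of all tested introns. With the authors' false discovery rate the shares were 14.5% of exons and 92% of introns, and with a quasi-binomial model 9% and 95.2%. Leaving out single libraries gave 3.7% to 4.5% of exons. Events of one gene share junctions and are not independent: with 1 event per gene and type, 2146 were called. The authors' deposited table holds 19411 events at their false discovery rate under 0.05 and the same difference, 15229 of them among the tested events.

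The shift also showed without calls. Median inclusion of the tested cassette exons fell from 80.1% ± 0.089 to 63.0% ± 0.574 between shScramble and shSON, and median intron retention rose from 3.62% ± 0.165 to 13.1% ± 0.382 (SD, n = 3). All shSON libraries lay beyond all shScramble libraries (exact two-sided permutation p = 0.1 for each, the smallest it allows). The size depends on the summary and on the read filter. Mean inclusion fell from 59.3% to 53.4%, and mean retention rose from 20.7% to 30.3%. Without a read filter the median shift was -4.97 points for exons and 23.81 for introns. The filter counts reads of each form over both groups. An exon fully included in shScramble can thus enter through skipping reads in shSON, which can enlarge the exon shift. The same shScramble libraries had a median exon inclusion of 80.1% over these events but 69.1% over those tested for shSRRM2.

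**Figure D2:**
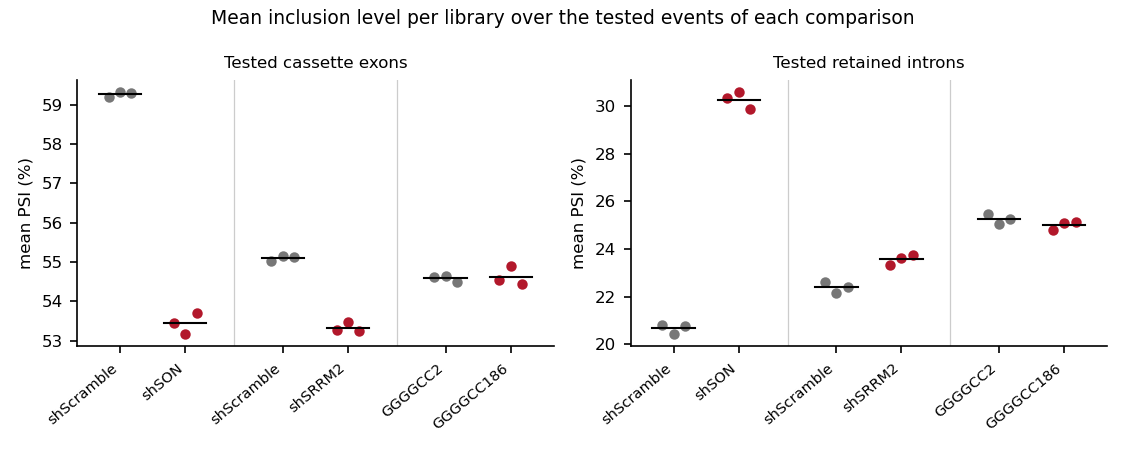
Mean percent spliced in (PSI, vertical axis, not starting at 0) over all tested cassette exons (left) and retained introns (right), 1 point per library and a line for the mean of 3. Each comparison has its own tested events, so shScramble appears at different levels. Exon inclusion averaged 53.4% in shSON against 59.3% in shScramble, and intron retention 30.3% against 20.7%.

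Retained introns in shSON lay between coding exons in several of the most changed genes. In MFSD3, a membrane transporter of the major facilitator superfamily, retention of the intron at chromosome 8, 144510508 to 144510597, rose from 4.2% ± 4.5 to 97.5% ± 4.3 (limma adjusted p = 4.14e-06, 33.0 reads per library). IFRD2 on chromosome 3 rose from 10.1% ± 7.1 to 97.2% ± 4.8 at 50289629 to 50289711. The PRPF40B intron is at chromosome 12, 49642676 to 49642929 (adjusted p = 1.2e-06, 23.0 reads per library). Introns of GALT, an enzyme of galactose metabolism (94.3% ± 9.9 to 13.4% ± 3.5), of the ribosomal protein gene RPL13A (86.0% ± 13.4 to 17.3% ± 3.0), of AAAS, which encodes a nuclear pore protein (100% ± 0.0 to 36.0% ± 15.9), and of ILK, the integrin-linked kinase (74.7% ± 27.5 to 17.8% ± 1.6), were retained less. Among skipped exons, CA11, a carbonic anhydrase relative, fell from 100% ± 0.0 to 2.1% ± 2.7, FXYD7, a brain regulator of the sodium pump, from 100% ± 0.0 to 4.3% ± 2.9, and SCAF1, an SR-related factor, from 100% ± 0.0 to 5.5% ± 3.0. The RNH1 exon, at chromosome 11, 504824 to 504996, is an annotated exon of the 5′ untranslated region. The few exons that rose included WDR17 (38.5% ± 23.7 to 96.7% ± 5.8), EPB41L1, a membrane skeleton protein of neurons (34.8% ± 20.7 to 84.8% ± 18.0), and PLPP1, a phospholipid phosphatase (45.3% ± 14.6 to 95.1% ± 8.6). Mean reads per library behind these events ran from 20.3 (PLPP1) to 134 (EPB41L1), so the percentages are coarse, and RPL13A, which has processed copies elsewhere in the genome, is uncertain. The EPB41L1 call was lost without shScramble replicate 2 or 3 or shSON replicate 1, and the PLPP1 call without shScramble replicate 1 or shSON replicate 1 or 3.

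Genes of the neuronal, mitochondrial and disease lists were among those called. Inclusion of an exonic segment of CYC1, the cytochrome c1 subunit of respiratory complex III, fell from 98.2% ± 2.2 to 16% ± 0.4 (638 reads per library, limma adjusted p = 2.13e-06), and NDUFV1 of complex I fell from 99.3% ± 1.2 to 38.5% ± 4.1. Retention of an NDUFB10 intron of 160 nt rose from 15.6% ± 3.9 to 58.5% ± 3.0. In the adhesion molecule L1CAM, inclusion fell from 87.9% ± 1.0 to 23.3% ± 3.6 (adjusted p = 1.81e-07), and in SYP, the synaptic vesicle protein synaptophysin, from 85.9% ± 2.2 to 55.7% ± 5.4. A 14 nt segment of DCTN1, the dynactin subunit mutated in motor neuron disease, fell from 55.5% ± 9.5 to 12.6% ± 2.5 (437 reads per library), and a UNC13A segment fell from 100% ± 0.0 to 16.2% ± 10.7 (15.3 reads per library). Retention of an intron in CFAP410, on chromosome 21 at 44330917 to 44331842, rose from 27.3% ± 0.5 to 78.9% ± 4.8. FLNA (100% ± 0.0 to 29.6% ± 3.4) and HDAC6 (88.2% ± 1.8 to 25.7% ± 2.6), both named in earlier SON depletion work, lost inclusion of an exonic segment.

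None of 16 gene lists fixed beforehand passed the test for an excess of genes with a called event in shSON over genes matched on tested events and reads (10000 random sets, one-sided permutation test). Targets named in earlier SON depletion work came closest, with 9 of 13 tested genes against 5.04 in matched sets (permutation p = 0.02, adjusted p = 0.32). Without matching, that list had an adjusted p of 0.011. The counts below are followed by the mean of matched sets in brackets. Several lists lay below it, but the test was one-sided for an excess, so a shortfall was not tested. Among neuronal lists, 18 of 61 synaptic vesicle and active zone genes (18.7) and 18 of 45 synaptic adhesion and scaffold genes (15.8) had a called event. So had 12 of 36 ion channels (11.3) and 21 of 73 microtubule and axonal transport genes (21.6). For RNA processing, the counts were 10 of 48 nuclear speckle proteins (15.4), 10 of 33 SR and SR-related factors (11.2) and 16 of 45 hnRNP and neuronal splicing regulators (14.1). They were 11 of 55 for spliceosome core genes (11) and 4 of 25 for genes prone to detained introns (8.7). The rest were 6 of 31 amyotrophic lateral sclerosis and frontotemporal dementia genes (9.96), 10 of 56 nucleocytoplasmic transport genes (15.1) and 17 of 65 autophagy and endolysosome genes (18.3). DNA repair had 21 of 60 genes (18.5), chromatin modifiers 27 of 79 (27.3) and the respiratory chain 7 of 56 (11.4). Chromatin modifiers with lower exon inclusion (20 genes) included SIRT2, a deacetylase of tubulin and histones, from 98.2% ± 1.8 to 31.1% ± 0.8. DNA repair genes included FANCG of the Fanconi anaemia pathway, from 98.9% ± 1.9 to 14.1% ± 1.3, and retention of an EME2 intron from 7.9% ± 6.3 to 93.9% ± 5.9. In the autophagy list, a WDR45 exon fell from 96.1% ± 1.8 to 25.5% ± 13 and retention of a ULK3 intron rose from 18.3% ± 7.1 to 100% ± 0.0.

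Skipped exons and retained introns in shSON sat among short introns. The introns before and after skipped exons had medians of 370 and 293 nt, against 2344 and 2372 nt for uncalled exons matched on reads (permutation test, two-sided, p = 1e-05, the smallest it can give, adjusted p = 4e-05 over 24 tests). Exons with higher inclusion instead followed long introns, with a median of 3358 nt against 2373 (adjusted p = 0.0047). Introns retained more had a median of 133 nt against 209, and those retained less 554 against 220 (adjusted p = 4e-05 for both). The skipped exons themselves did not differ in length, with a median of 122 nt for both kinds (adjusted p = 0.94), nor passed the test for a length divisible by 3 (37.7% against 38.5%, adjusted p = 0.40). The permutation shuffled single exons and introns, and those of 1 gene are not independent, so these p-values are likely too small. Matching was on reads alone. Inclusion in shScramble was not matched, and events with room to fall differ in it from those with room to rise. Part of the length differences may follow from that. GC content was not analysed here.

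**Figure D3:**
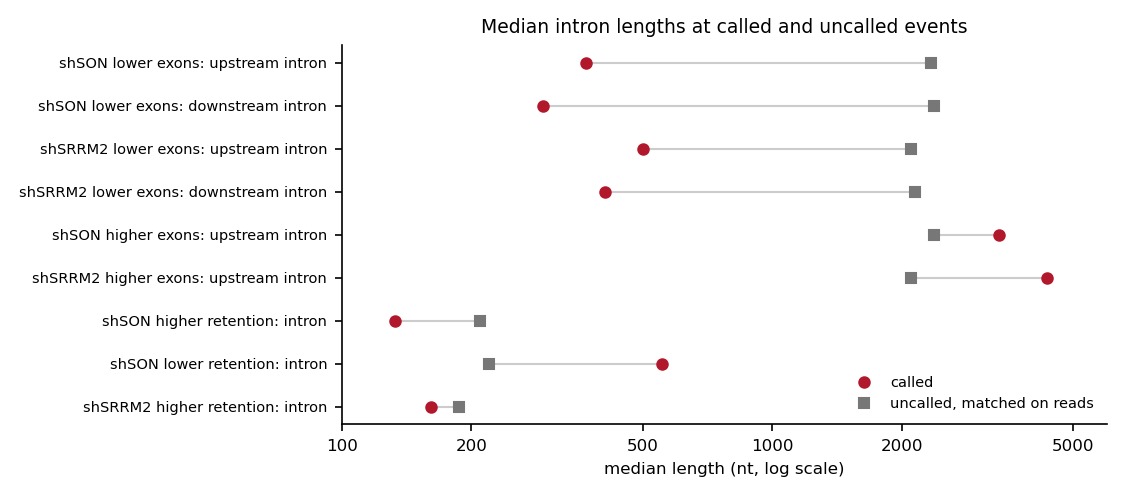
Median intron length in nucleotides (horizontal log axis) at called events (circles) and at uncalled events matched on reads (squares). Introns around exons skipped in shSON had medians of 370 and 293 nt against 2344 and 2372, those around exons skipped in shSRRM2 500 and 409 against 2102 and 2144, and introns retained more in shSON 133 against 209.

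Junction-read abundance, a proxy for expression, changed in 2933 of 10973 genes in shSON (1274 higher, 1659 lower, limma adjusted p under 0.05), with 730 changed at least 2-fold. With reads summed over all events of a gene, 4055 of 11819 genes changed and 475 of them at least 2-fold. Of 13 measured targets of earlier SON depletion work, 9 were lower and none higher (10 lower adjusted over the list alone). They included PFKL, the liver type of the glycolytic enzyme phosphofructokinase (log2 change -2.09, SE 0.16). The autophagy and endolysosome list had 18 of 69 genes higher and 12 lower (18 and 15 adjusted over the list alone), with the lysosomal channel MCOLN1 (-2.50, SE 0.25) and the tethering subunit VPS16 (-1.75, SE 0.17) among the lower ones. Of 81 chromatin modifiers, 19 were lower and 5 higher, the same counts adjusted over the list alone, led by HDAC5 (-1.62) and HDAC6 (-1.53). In the heat shock list, HSP90AA1, the inducible cytosolic HSP90, rose by 1.69 (SE 0.08, 529 to 1700 RPM), while HSPH1 fell by 0.58. Of the p53 response, 3 of 13 genes were lower and none higher (3 adjusted over the list alone), including BAX (-0.78). Neuron markers stayed well represented, with 4 of 15 higher, 1 lower and the same counts adjusted over the list alone. INA rose by 0.64 and NEFM by 0.55, while the vesicular glutamate transporter SLC17A7 fell by 1.26. Each gene is read at its most-read event, so a change in the use of that event can move its value. NEFM had 4200 RPM in shScramble here but 2920 in the shSRRM2 comparison, so it was read at different events. No microglia or GABAergic neuron marker was measurable, and the 4 measured genes of proliferating cells gave 2 lower (4 adjusted over the list alone).

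The second comparison asked the same of SRRM2. Called events of any type and direction lay in 520 of 9780 genes (5.32%), with cassette exons called in 424 of 8131 genes and introns in 100 of 3196, and most were skipped exons. Of 810 called cassette exons, 748 had lower and 62 higher inclusion, and of 117 called introns 105 were retained more and 12 less. DTX3, a Deltex-type ubiquitin ligase, had one of the largest losses, from 95.6% ± 2.5 to 14.3% ± 4.2 (SD, n = 3, 199 reads per library, limma adjusted p = 1.56e-08), at chromosome 12, 57606884 to 57607017. Alternative 3′ splice sites (2 higher and 29 lower), alternative 5′ splice sites (11 and 39) and mutually exclusive exons (36 and 38) brought the total to 1082 of 74705 events. Higher inclusion made up 7.7% of called exons (exact 95% binomial interval 5.9 to 9.7), against 43.6% of tested exons, and 89.7% of called introns (82.8 to 94.6), against 58.8%. These shares were 25.6% and 70.4% with the authors' false discovery rate, and 12.7% and 82.4% with a quasi-binomial model. Median exon inclusion fell from 69.1% ± 0.347 to 63.3% ± 0.424, and median retention rose from 4.49% ± 0.090 to 5.68% ± 0.201 (exact two-sided permutation p = 0.1 for each, the smallest it allows). The exon shift of -5.88 points was -1.76 for the mean and -1.93 without a read filter, and the intron shift of 1.19 was 3.58 without a filter. Here too the filter let events enter through reads of the knockdown libraries. The count of 1082 moved strongly with the model: 39 events without the trend of variance on sampling error and 1968 with a quasi-binomial model. The count fell to 484, 554 and 510 without shSRRM2 replicates 1, 2 and 3, while the authors' deposited table holds 7907. Genes with a called event fell from 520 to 249, 288 and 267 in these 3 fits, and to 14 without the variance trend. Called mutually exclusive exons fell from 74 to 47 without shSRRM2 replicate 2. Leaving out single libraries took the alternative 3′ splice sites from 31 to between 6 (without shSRRM2 replicate 1) and 18 (without shScramble replicate 2), and the alternative 5′ splice sites from 50 to between 6 (without shSRRM2 replicate 3) and 20 (without shScramble replicate 3). Of 66 events named in shSRRM2 by the rule, 65 lost the call without the variance trend, and that of DTX3 kept it.

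**Figure D4:**
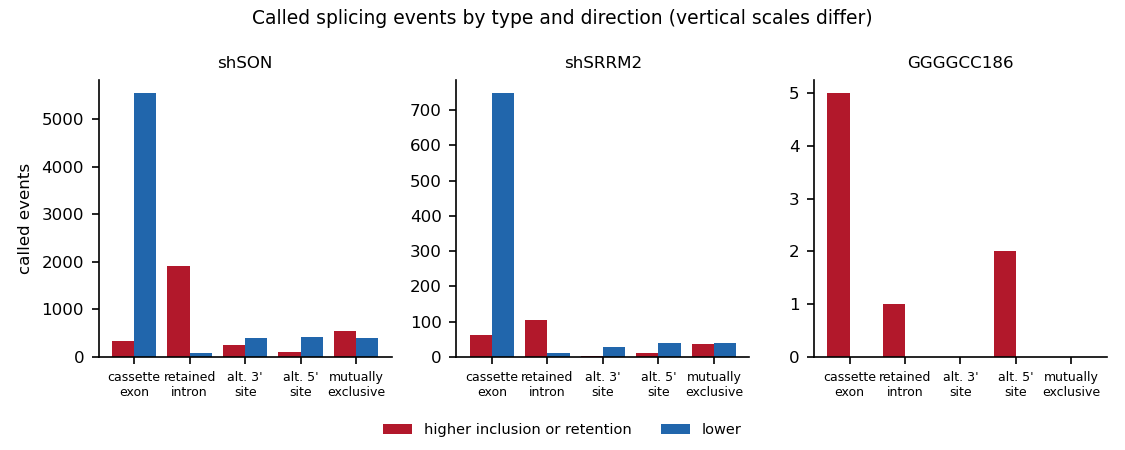
Number of called events (vertical axis from 0, with a different scale in each panel) by event type, with higher inclusion or retention in red and lower in blue. The shSON panel reaches 5551 skipped exons and 1902 retained introns, the shSRRM2 panel 748 and 105, and GGGGCC186 has 8 events in all.

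Other skipped segments in shSRRM2 lay in KIAA0895L (90.5% ± 16.5 to 5.6% ± 3.3), in TSPOAP1, a binding partner of active zone proteins (96.6% ± 6.0 to 23.7% ± 4.3), and in an exon of the 5′ untranslated region of the ubiquitin ligase RNF167 (76.1% ± 22.0 to 6.1% ± 5.5). Exons of RAP1A, a small GTPase (15.9% ± 8.4 to 89.4% ± 18.4), and of APBA1, a synaptic adaptor (36.9% ± 33.9 to 92.0% ± 7.0 for a coding exon of 33 nt), gained inclusion, as did C2orf80 (49.7% ± 5.1 to 98.5% ± 2.6). Retention rose in CDH24, a cadherin (14.1% ± 8.4 to 66.8% ± 3.5, 110 reads per library, adjusted p = 3.03e-05), FAHD2A (40.8% ± 12.5 to 94.4% ± 9.6) and the death receptor TNFRSF25 (18.2% ± 10.7 to 72.8% ± 9.9). It fell in CDK20 (76.3% ± 21.4 to 28.6% ± 14.6), COMMD3 (83.5% ± 11.2 to 43.8% ± 14.1) and SNHG1, a host gene of small nucleolar RNAs (47.0% ± 12.2 to 15.6% ± 6.6). Within SRRM2 itself, retention of the intron at chromosome 16, 2757580 to 2757780, was 10.7% ± 5.5 in shSRRM2 against 0.3% ± 0.4 (adjusted p = 0.00187). None of these calls was kept without the variance trend. Those of CDH24, KIAA0895L, TSPOAP1, RNF167 and C2orf80 were kept whichever library was left out, where the event could be tested. The TNFRSF25 call was lost each time, those of APBA1, CDK20 and COMMD3 each time except without shScramble replicate 2, FAHD2A without shScramble replicate 2 or 3 or shSRRM2 replicate 1, RAP1A without shScramble replicate 1 or 2 or shSRRM2 replicate 3, SNHG1 without shScramble replicate 1 or shSRRM2 replicate 1 or 3, and SRRM2 without shSRRM2 replicate 1 or 2.

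Genes of the synaptic, splicing regulator and chromatin lists were among those called in shSRRM2. The first of a pair of mutually exclusive coding exons of SNAP25, a SNARE protein of vesicle release, rose from 42.1% ± 2.2 to 70.5% ± 2.7 (1209 reads per library, limma adjusted p = 2.69e-08), at chromosome 20, 10292882 to 10292999. A CELF3 segment, in a gene for a neuronal splicing regulator, fell from 36.7% ± 2.5 to 10.4% ± 0.1 (889 reads per library, adjusted p = 9.48e-09). A coding exon of 24 nt fell in SHANK1, a postsynaptic scaffold (48.7% ± 2.8 to 29.2% ± 4.7). The first exon of a mutually exclusive pair in MAPT, which encodes the microtubule protein tau, fell from 50.7% ± 20.1 to 24.3% ± 6.2 (adjusted p = 0.0335). BIN1, a membrane-bending endocytic adaptor, fell from 74.9% ± 3.7 to 49.8% ± 3.7, and a coding exon of the histone demethylase KDM2B from 77.5% ± 5.2 to 40% ± 5.2. All 6 calls were lost without the variance trend, and that of MAPT also without any single library except shScramble replicate 1, while the others were kept whichever library was left out. Of the lists, 10 of 47 synaptic adhesion and scaffold genes had a called event against 4.19 in matched sets (permutation p = 0.0064, adjusted p = 0.10), and 9 of 63 synaptic vesicle and active zone genes against 4.59 (p = 0.032, adjusted p = 0.25), so neither passed. With the authors' calls the vesicle list had an adjusted p of 0.016, and without matching the adhesion and vesicle lists had 0.0048 and 0.046. Counts elsewhere, with the mean of matched sets in brackets, were 6 of 54 spliceosome core genes (2.93) and 6 of 44 hnRNP and neuronal splicing regulators (4.59). They were 8 of 70 microtubule genes (7.17), 8 of 77 chromatin modifiers (6.74), 3 of 48 speckle proteins (4.2) and 3 of 30 disease genes (2.76). DNA repair and the respiratory chain had 3 of 58 genes each (3.39 and 3.19). The rest were 2 of 37 ion channels (2.54), 2 of 13 earlier SON targets (1.19) and 2 of 25 genes prone to detained introns (2.62). SR factors (34 tested), nucleocytoplasmic transport (57) and autophagy (64) had 1 each, against 3.4, 3.72 and 4.23 in matched sets. The last was the autophagy gene ATG10 (100% ± 0.0 to 33.9% ± 22.9).

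Exons skipped in shSRRM2 had flanking introns with medians of 500 and 409 nt against 2102 and 2144 nt for matched exons (permutation test, two-sided, adjusted p = 4e-05). They were slightly longer than matched exons (134 against 122 nt, adjusted p = 0.00051). Exons with higher inclusion followed introns with a median of 4362 nt against 2102 (adjusted p = 0.00017). Introns retained more had a median of 161 nt against 187, which did not pass (adjusted p = 0.36). Inclusion in shScramble was not matched here either. Exons of 27 nt or less made up 3.2% of the skipped exons against 1.8% (adjusted p = 0.024), but with the authors' calls the shares were 2.1% and 2.2%, and the call was lost.

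Junction-read abundance changed in 3107 of 11057 genes in shSRRM2 (1459 higher, 1648 lower), with 573 changed at least 2-fold. Reads summed over all events of a gene gave 4318 of 11855 and 372. The neurofilament genes NEFL (log2 change -1.31, SE 0.05, 4210 to 1690 RPM) and NEFM (-1.01, SE 0.07) fell, as did DCX, a microtubule protein of young neurons (-0.76), in a neuron list with 5 of 15 genes higher and 4 lower (6 and 4 adjusted over the list alone). Respiratory chain genes rose more often than they fell, with 26 of 62 higher and 3 lower (28 and 3 adjusted over the list alone), while in shSON 18 of 61 were higher and 12 lower (22 and 13 over the list alone). NDUFA10, with a retained intron (14.6% ± 1.2 to 29.5% ± 5.6), was among the lower ones (-0.97, SE 0.13). HSP90AA1 rose here too, by 1.52 (SE 0.07), and MAP4, a microtubule protein, by 1.73. The channel HCN2 (-2.80) and the histone demethylase KDM4A (-1.66) were lower, and HNRNPA1, an hnRNP that binds pre-mRNA and has many processed copies in the genome, fell by 1.04 and is uncertain. The p53 list again had 3 of 13 genes lower and none higher (3 over the list alone). Of marker genes, SLC1A2 of astrocytes fell in both shSON (-0.58) and shSRRM2 (-0.56), and LIN28B of pluripotent cells rose in shSRRM2 (0.81). Because each gene is read at its deepest splicing event, a change in the use of that event can move its value. NEFM was read at different events in shSON and shSRRM2, so its rise and fall cannot be set side by side.

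Direct comparison of the knockdowns asked where they differed. Exon skipping and intron retention went further in shSON than in shSRRM2. Of 3601 cassette exons called between them, 3209 had higher inclusion in shSRRM2, and of 1505 introns 1441 were retained less in shSRRM2, within 6297 called of 68531 events (limma, 1996 genes). Among events tested against shScramble in both, 668 were called in both, in 335 genes, and 663 of these went the same way (99.3%). Both fell for 552 events, against 52.86 for independent lists, and both rose for 111, against 7.6. Independent lists take no account of reads or inclusion level, which affect calls in both. KIAA0895L (1.8% ± 3.0 in shSON and 5.6% ± 3.3 in shSRRM2, from 90.5% ± 16.5), an alternative 3′ splice site of the ubiquitin ligase gene RNF44 (16.2% ± 5.4 and 25.8% ± 15.7, from 100% ± 0.0) and retention in RP11-803J6.1 (94.9% ± 8.9 and 93.0% ± 12.2, from 20.1% ± 16) had the largest changes in common, with RP11-216L13.18 at 13.7% ± 23.8 and 22.9% ± 19.6 from 100% ± 0.0. In shSRRM2 the call of RNF44 was lost without shScramble replicate 1 or shSRRM2 replicate 1 or 2, and those of RP11-216L13.18 without shScramble replicate 3 or shSRRM2 replicate 3. Shared exons moved by a median of 42.3 points in shSON and 24.0 in shSRRM2, and 423 of 516 moved further in shSON. For shared introns the medians were 49.7 and 24.1 points, with 65 of 72 larger in shSON. The counts and sizes were not adjusted for the depth of knockdown. By junction reads, SON was at 31.8% of control in shSON and SRRM2 at 44.6% in shSRRM2.

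Both knockdowns used the same shScramble libraries, which raises any likeness between them. Across 9179 genes, which are not independent replicates, the correlation of effects on the log odds scale was 0.583 with 1 event per gene (Spearman 0.548), and unchanged groups simulated against the same controls gave 0.5 on average and 0.521 at most over 100 simulations. The covariance was 1.132 against 0.39 simulated, a difference of 0.741. Effects had the same sign for 69.3% of genes, against 66.7% in the simulated groups. With 3 control libraries the controls could not be split into separate sets of at least 2, so part of the excess of shared calls may come from them.

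The repeat comparison asked whether 186 GGGGCC repeats change splicing against 2. Only 8 events in 4 genes were called, all with higher inclusion in GGGGCC186, out of 83035 tested in 10214 genes. Among them were 4 segments of APC, a regulator of Wnt signalling. The coding exon at chromosome 5, 112754873 to 112755025, went from 81.6% ± 0.8 to 100% ± 0.0 (299 reads per library, limma adjusted p = 2.62e-05), and a segment at 112738328 to 112738460 went from 5.1% ± 8.9 to 100% ± 0.0 (21.5 reads, adjusted p = 0.0211). In NDUFB2, of respiratory complex I, an alternative 5′ splice site at chromosome 7, 140697075 to 140697172, went from 40.9% ± 6.2 to 100% ± 0.0. A coding exon of PPOX, an enzyme of heme synthesis, went from 14.6% ± 15.6 to 91.5% ± 10.1 (adjusted p = 0.0495), and an intron not in the annotation within EEF1A1, a translation elongation factor with many processed copies in the genome, from 37.0% ± 1.5 to 97.1% ± 5.0 (adjusted p = 0.000542). The direction of these changes rests on the order of the group names in the deposited tables, which no targeted gene could check.

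No broad change accompanied these events. Median exon inclusion was 68.2% ± 0.195 in GGGGCC2 and 68.3% ± 0.845 in GGGGCC186 (exact two-sided permutation p = 0.9), and median retention 5.5% ± 0.156 and 5.31% ± 0.259 (p = 0.4). Of 39770 tested exons, 1974 (4.96%) had an unadjusted limma p under 0.05, as had 402 of 8384 introns, 553 alternative 3′ splice sites, 396 alternative 5′ splice sites and 687 mutually exclusive exon pairs. No alternative 3′ splice site or mutually exclusive pair was called. The libraries of the groups did not overlap for 9.7% of tested events, where chance gives 10% for 3 against 3. Other models gave 0 events (no variance trend), 102 (quasi-binomial) and 3040 (the authors' false discovery rate on the tested events, with the difference computed from the reads). The authors' deposited table lists 5236 events, 2565 higher and 2671 lower, and 52.1% of those among the tested events had libraries that did not overlap. Sensitivity to rare changes was low for exons at the spread between libraries set in the simulations. With 200 changed events among these exons, limma called 4% of changes of 0.3 in PSI and the quasi-binomial model 14%. For introns the shares were 34% and 46%, and 78.4% with limma above 100 reads. Calls moved between 4 and 12 when single libraries were left out, with 4 without GGGGCC2 replicate 1 and 5 without GGGGCC186 replicate 3, and with 1 event per gene and type none was called. Of the events named for APC (at 112738328), PPOX, EEF1A1 and NDUFB2, only that of EEF1A1 kept its call whichever library was left out. The PPOX exon lost its call each time, the APC segment each time except without GGGGCC2 replicate 3, and the NDUFB2 site each time except without GGGGCC186 replicate 1. The better-covered APC coding exon at 112754873, the other called APC segments and a second, better-covered NDUFB2 site were not followed in this way. That site, at 140697075 to 140697277, went from 64.8% ± 9.2 to 100% ± 0.0 (95.8 reads, limma adjusted p = 0.000555). In all, 1 alternative 5′ splice site was still called without GGGGCC2 replicate 1 or GGGGCC186 replicate 2 or 3, and its gene was not looked up. Abundance passed for 2 of 11527 genes (533 at an unadjusted p under 0.05), and no member of the 16 gene lists or of the cell type and response lists passed over all genes. Adjusted over the list alone, 1 ion channel gene was lower and no other list had a member that passed.

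Events changed by the knockdowns were then read in the repeat neurons. Of 49236 events tested in both GGGGCC186 and shSON, 1 was called in both, in the opposite direction, where independent lists give 0.25 higher in both and 0.4 in opposite directions. Directions here rest on the assumed order of the repeat groups, and the other order would turn each of them. With shSRRM2 none of 49103 was shared, at 4 GGGGCC186 calls in the common set. Over the shSON-called events of 1900 genes, signed by the shSON direction, inclusion in GGGGCC186 moved by -0.104 points against 30.06 in shSON. The highest other split of the 6 libraries reached 0.194. Genes moving in the shSON direction made up 47.9% (exact 95% binomial interval 45.6 to 50.2), or 52.1% with the groups in the other order. Over 445 genes called in shSRRM2 the change was 0.36 points against 24.02, with 49.0% in the same direction (44.3 to 53.7), or 51% with the other order. For introns alone the change was -0.514 points over 824 genes for shSON, with 44.4% in the same direction (41 to 47.9, or 55.6% with the other order), and -1.391 points over 81 genes for shSRRM2, with 40.7% (29.9 to 52.2, or 59.3%). In each case 2 of the 10 splits of the libraries gave a change as large, and the intervals treat genes as independent and leave out the spread between libraries. With the authors' calls, 335 events were shared with shSON, 183 in the same direction, and over 1 event per gene 147 of 270 (54.4%, 48.3 to 60.5, exact binomial p = 0.161). Of the shared events 125 were lower in both, against 70.02 for independent lists, 58 higher in both, against 47.88, and 152 opposite, against 116.3 (odds ratio of sharing 1.59, Fisher's exact p = 3.15e-12). With shSRRM2 the authors' calls shared 194, with 112 in the same direction and 92 of 163 genes (exact binomial p = 0.117). Here 84 were lower in both, against 33.29, 28 higher, against 15.54, and 82 opposite, against 47.94 (odds ratio 2.24, Fisher's exact p = 1.49e-20). Both overlaps were thus above independence with the authors' calls, in the same and in opposite directions alike, although events that share junctions are not independent and make these p-values too small. The lists were not matched on reads or inclusion level, which affect whether an event can be called in any comparison. An overlap above independence therefore does not show a common effect of repeats and knockdown. The difference of effects itself, fitted over 12 libraries, was called for 4312 of 81382 events against shSON and 286 of 80101 against shSRRM2. Repeat and knockdown neurons also differed in neuron age and experiment, which these counts cannot separate.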

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

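Tests chosen only after the result was seen were the split counts of called splicing events, the share of small p-values in GGGGCC186, the SON level in shSRRM2 and the fall of spliced reads at retained introns. The effects of the knockdowns differed from each other at 6297 events tested directly between shSRRM2 and shSON. The effect of GGGGCC186 differed from that of shSON at 4312 events and from that of shSRRM2 at 286, each by a test of the difference itself. The repeat neurons were at day 10 and the knockdown neurons at day 14, in separate experiments. A difference between these effects cannot be told apart from one of neuron age or experiment.

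For the difference from shSON, 4 of 100 splits of the libraries within both experiments called as many events (highest other 4427), a share under 0.05. For the difference from shSRRM2, 7 of 100 did (highest other 320). In both cases other groupings gave a result as large. Every split as large was among the 12 and 11 splits that kept the knockdown libraries in their own groups. Splits that mixed them called at most 2 and 8 events, so these counts follow the knockdowns rather than the repeat length. The shares depend on how many splits kept the knockdown groups, so neither decides on an effect of repeat length. The 10 splits of 6 libraries are too few for a share under 0.05. The real counts were 9953 in shSON (highest other 2, with 1 split as large), 1082 in shSRRM2 (highest other 2, 1 split), 6297 between the knockdowns (highest other 2, 1 split) and 8 in GGGGCC186 (highest other 18, 3 splits). For abundance they were 2933 in shSON (highest other 0, 1 split), 3107 in shSRRM2 (highest other 1, 1 split) and 2 in GGGGCC186 (highest other 4, 5 splits).

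Higher intron retention in shSON, with 1902 introns retained more, could come from genomic DNA, from precursor RNA carried over, or from fewer spliced reads over a constant intron background. The last was argued against: depth-scaled intron reads of the called introns rose by a median of 1.74 on the log2 scale, and 94.5% of them had more. DNA as the sole source was argued against by the spliced reads of the same introns, whose median log2 change was -1.53, but a contribution stays open, because the gain in intron reads was 0.8 times as large in the highest as in the lowest quintile of control spliced reads (medians 4.8 and 6.25), as DNA would give. The read filter admits weakly spliced introns only if they are rich in intron reads, which limits that comparison. The medians of 1.74 and -1.53 come from introns called for higher retention in the same libraries. That choice favours more intron reads and fewer spliced reads, so both sizes may be too large. The gains of 4.8 and 6.25 reads are over all tested introns of those quintiles. Precursor RNA also stays open, since 15.2% of 1155 well-measured other introns in 404 genes had an upper limit below 50% of the change of the called intron, between the bounds set for it.

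The few calls in GGGGCC186 against 5236 in the authors' deposited table may reflect differences between libraries unrelated to repeat length, or too little sensitivity. A shSON-like change of 5% or more was argued against, as the mean change over shSON-called events was -0.34% of the shSON change. With the quasi-binomial model the real split called 102 events and the highest other split 83, which decides neither way. Cassette exons with an unadjusted p under 0.05 made up 4.96%, about the chance share, but rare changes stay open because simulated changes of 0.3 were called in 4% of exons and 34% of introns.

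The 663 events called in both knockdowns with the same direction could come from the shared shScramble libraries or from lower SON in shSRRM2. Shared controls as the whole source were argued against by a covariance 2.68 times the highest simulated one, though part of the overlap may still come from them. Lower SON RNA was argued against by the lower 95% limit of its log2 change in shSRRM2, -0.09, from its most-read splicing event. SON protein was not measured, so a loss of SON function stays open. No other biological explanation of the overlap was tested.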

How the results depend on the processing

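The mean in place of the median PSI was an alternative chosen after seeing the data; all others were planned. Of 348 values for main results, 261 kept their direction and side of the threshold or moved little, 80 moved, 6 became stronger and 1 reversed. Of 1815 values for named events, 318 lost the call and none changed direction. In shSRRM2, 65 of 66 lost it without the variance trend, and 37 of 66, 31 of 64 and 36 of 64 without shSRRM2 replicates 1, 2 and 3 and 22 of 63, 22 of 63 and 28 of 65 without shScramble replicates 1, 2 and 3. In shSON, 8 of 86 lost it without the trend and between 4 and 8 when single libraries were left out, among them EPB41L1, PLPP1 and the MAP4 alternative 3′ splice site. Of 1588 for gene abundance 79 lost the call. Of 165 other counts, 66 moved. The causes were not tested except where fewer events were tested. No paired analysis was possible because the values in a cell carry no replicate number. With the authors' false discovery rate and the difference computed from the reads, called events were 15189 in shSON, 5248 in shSRRM2 (3334 exons, 504 introns) and 3040 in GGGGCC186 (1599 and 281). The authors' listed differences gave 15229, 5273 and 3057 from the same tests, as 40, 25 and 17 events listed at 0.1 were just below it when computed. Same-direction overlaps were 2325, 183 and 112. The quasi-binomial model gave 1968 (1414 and 188) in shSRRM2 and 102 (46 and 10) in GGGGCC186, and no variance trend gave 39 (33 and 0) and 0 (0 and 0). Without a read filter the counts were 1874 (1317 exons) and 129 (86 and 9). A PSI difference of 0.2 gave 641 (492 and 70) in shSRRM2. With 1 event per gene and type they were 2146 (880 and 675) in shSON, 260 (147 and 60) in shSRRM2 and 0 (0 and 0) in GGGGCC186. Adding 1 read gave 18 (14 exons) in GGGGCC186, and a mean of 20 reads gave 3 exons.

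Median shifts in PSI for shSON exons were -15.88 points with 20 reads, -4.97 without a filter and -5.82 for the mean, and for introns 7.76 and 23.81 with the first pair of settings. In shSRRM2 they were -1.93 without a filter and -1.76 for the mean for exons, and 0.97 with 20 reads and 3.58 without a filter for introns. GGGGCC186 introns gave -0.57 without a filter. GGGGCC186 abundance called 1 gene without a filter, 1 with 0.25 RPM added and 0 with reads summed over events. Stronger results were the earlier SON targets without matching (ratio 2.89, adjusted p = 0.0112), the vesicle list in shSRRM2 with the authors' calls (1.64, adjusted p = 0.016) and without matching (2.68, adjusted p = 0.0464), the adhesion list without matching (4.06, adjusted p = 0.0048), and with the authors' calls the downstream introns of exons rising in shSON (log2 difference 0.24, adjusted p = 0.0002) and the length of introns retained more in shSRRM2 (-0.24, adjusted p = 0.00111). The share of skipped exons of 27 nt or less in shSRRM2 reversed with the authors' calls (-0.15 points, adjusted p = 0.638).

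Leaving out single libraries moved the shSON shift from -17.96 to -17.16 for exons and 9.17 to 9.95 for introns. The shSRRM2 counts ranged from 484 to 808 (367 to 644 exons, 49 to 87 introns), with 484, 554 and 510 without shSRRM2 replicates 1, 2 and 3. The GGGGCC186 counts ranged from 4 to 12 (2 to 8 exons, 1 to 4 introns), with 4 without GGGGCC2 replicate 1 and 5 without GGGGCC186 replicate 3. Exons alone fell to 2 without GGGGCC186 replicate 1 and 3 without GGGGCC2 replicate 3 and rose to 8 without GGGGCC186 replicate 2. Abundance calls in GGGGCC186 ranged from 0 (without GGGGCC2 replicate 1 or GGGGCC186 replicate 3) to 4 (without GGGGCC186 replicate 1). Depth limits the events below 100 reads most.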

Other observations

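No test in this part was chosen after its result was seen. Abundance changed in further lists, and differences between the knockdowns were not tested for them. In shSON, synaptic vesicle genes had 5 of 66 higher and 15 lower (5 and 16 adjusted over the list alone), among them AP2M1, a subunit of the clathrin adaptor AP-2 (log2 change -0.77, SE 0.07, limma adjusted p = 2.61e-08), and the SNARE gene STX1A (-0.92, SE 0.11). Spliceosome core genes had 16 of 59 higher and 6 lower (18 and 7 over the list alone), with PRPF40B at -2.19 and DDX23 at -0.92, and speckle proteins 9 of 50 higher and 1, SON itself, lower (7 and 1). DNA repair genes had 2 of 62 higher and 10 lower (2 and 8), including XRCC1 (-1.66). In shSRRM2, synaptic vesicle genes had 14 of 66 higher and 12 lower (14 and 14) and spliceosome core genes 5 of 59 higher and 5 lower (1 and 3). DNA repair there had 2 higher and 9 lower (2 and 9), and speckle proteins 7 higher and 10 lower (7 and 10), including the SR protein kinase SRPK2 (-1.03) and the splicing regulator TRA2B (-0.67). PFN1, the actin-binding profilin mutated in familial disease, rose in both, by 1.05 and 1.16, with 7 of 32 disease genes higher and 2 lower in shSON (7 and 2) and 11 higher and 7 lower in shSRRM2 (12 and 7).

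Marker and response lists were small. Glutamatergic markers had 1 of 5 higher and 2 lower in shSON (2 and 2 adjusted over the list alone), with SLC17A6 at 0.60 and SLC17A7 at -1.26, and 0 higher and 1 lower in shSRRM2 (0 and 1), SLC17A6 at -0.58. Neural progenitor markers (2 measured in the knockdowns) and the 1 measured oligodendrocyte lineage marker had no member past limma in any comparison. The fibroblast marker THY1, which neurons also express, was lower in shSON (-0.66). Stress and unfolded protein genes had 2 of 15 higher and 3 lower in shSON (2 and 3), including the chaperone HSPA5 (-0.66), and 1 of 14 higher and 1 lower in shSRRM2 (1 and 1). Heat shock genes in shSRRM2 had 1 of 8 higher and 3 lower (1 and 3), including DNAJB1 (-0.60). Interferon genes had 1 of 5 higher (IRF9, 1.26) and 1 lower (STAT2, -0.84) in shSON (1 and 1), and 1 lower in shSRRM2 (3 over the list alone).

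One hypothesis was tested: genes whose introns are retained more in shSON may have fewer junction reads. Over 970 genes with a called rise in retention, the median log2 change in junction reads from other events was -0.5, against 0.01 over 2222 other genes with tested introns. Sets matched on reads had a median of -0.12 (permutation test, one-sided, p = 1e-05, the smallest it can give). Of the retained genes 507 were called lower and 44 higher, against 396 and 312 of the others. The direction was as the hypothesis requires, but the other events of a gene can include the splice junction of the retained intron. Retention alone can then lower these reads, so a fall in RNA level was not told apart from it. No test tied the change of reads to the intron itself, and the same libraries gave both measures.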
